A study of Rattus norvegicus with 4 samples.

How the data were processed

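Polyadenylated RNA was sequenced from primary cultures of rat cortical neurons, 2 control and 2 treated with N-methyl-D-aspartate (NMDA), the agonist that gives the NMDA class of glutamate receptor its name. Per the labels' protocols, the cortices came from embryos at day 18 and the libraries were strand-specific. NMDA was given at 10 µM. The protocols list exposures of 4 and 24 hours and culture ages of 15 and 21 days in vitro, without saying which applies to these 4 libraries. The protein interaction profiling of the same study was not analysed here.

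The deposited counts per library are whole numbers of reads over 32883 Ensembl gene IDs, with 5 summary lines. Per the submitters' processing notes, cutadapt 1.2.1, STAR 2.4.0, HTSeq, DESeq and DESeq2 were used, with genome build rn6. Their settings, the annotation release and whether reads were counted by strand are not given in the sources used here, so genes that overlap or lie antisense to another are uncertain. The summary lines held 48.1% ± 1.64 (SD, n = 2) of the listed reads in control and 46.3% ± 3.14 in NMDA. They include reads aligned to several places, so levels of genes with near-identical copies are uncertain too. Gene counts totalled 57733088 in control 1, 93077519 in control 2, 35706926 in NMDA 1 and 14564706 in NMDA 2, and 3 counts amount to 0.0520, 0.0322, 0.0840 and 0.206 CPM (gene counts scaled to a common library total). The authors also deposited normalized values per gene and library, a depth-scaled signal. Counts divided by these values gave 1 constant per library, in the same order 1.40, 2.39, 0.836 and 0.363, which matched DESeq2 size factors computed over all lines, summary lines included. The authors' deposited table of the comparison lists 15352 genes and 3 summary lines, with log2 fold changes and their standard errors, a test statistic (a score), p-values and adjusted p-values, per the file headers.

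The files do not pair the IDs with gene names. The RefSeq gene table of assembly GRCr8 used here held no Ensembl IDs, so none of the 32883 IDs could be matched to a name. The 31 gene lists drawn up for the comparison were therefore not tested, and the NMDA receptor subunit and activity-regulated genes that were to check the treatment labels were not looked up. The labels are taken as given. The rule for named genes took the 8 largest fold changes in each direction among named genes with an adjusted p under 0.05, an average log2 CPM of 3 or more and no overlap between the groups' libraries, along with members of the lists. With no names, its other criteria were applied to IDs and only the first 2 in each direction are given.

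The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the gene counts of all 4 libraries, two-sided, with group as the only term, TMM scaling and edgeR's default expression filter, which kept 15448 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Summary lines were left out of library totals and tests. The CPM of genes uses the TMM-scaled total, and that of 3 counts the plain total; log2 CPM values of single libraries have a prior count of 2. Standard errors of log2 fold changes are the size of the fold change divided by the square root of the F value.

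The test was tested on simulated data. In 10 draws, counts for the 15448 genes were drawn from their real mean levels and library sizes with 200 genes changed. With a dispersion per gene, 47.8% of 2-fold increases and 38.8% of 2-fold decreases were called, and 91.8% and 78.8% of 4-fold ones. Of all calls 8.86% were false, above the nominal rate, while 5.00% of unchanged genes had an unadjusted p under 0.05. With dispersions on their trend with level, 3.64% of calls were false.

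Replicate numbers 1 and 2 occur in both groups, but the labels do not say that they mark a shared culture or day. Nothing says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom over genes of 48.1 or more.

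The test, the rule for named genes and these alternatives were fixed before the data were examined: DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's legacy fit, 4 other scalings, no filter and a stricter one, 2 other thresholds, the replicate number as a block, and leaving out each library. Thinning of all libraries to the smallest total, a scaling that varies with level (loess offsets) and a crossed block were added after seeing the data.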

Results

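The study asked how excitotoxicity, the damage to neurons from overactive glutamate receptors, changes transcript abundance in cultured rat cortical neurons. Libraries of polyadenylated RNA were compared between 2 control and 2 NMDA-treated samples. Gene counts totalled 57733088 and 93077519 in control 1 and 2, and 35706926 and 14564706 in NMDA 1 and 2, so both treated libraries were shallower than both controls. Reads assigned to genes made up 51.9% ± 1.64 (SD, n = 2) of the listed reads in control and 53.7% ± 3.14 in NMDA. After thinning to the smallest library, 17639 ± 79.9 genes had at least 1 count in control and 17901 ± 230 in NMDA. Across the 15448 tested genes, which are not independent replicates, log2 CPM correlated at r = 0.989 between the control libraries and 0.975 between the NMDA libraries. The 4 pairings of a control with an NMDA library gave r between 0.955 and 0.961.

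In NMDA, 1047 genes were called higher than in control and 328 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Together they were 8.90% of those tested, and they are given below as genes that rose and genes that fell. The median log2 fold change was 1.80 among the genes that rose and -1.06 among those that fell. Of the genes that rose, 1044 had both NMDA libraries above both controls, and all 328 that fell had both NMDA libraries below both controls. Of all tested genes, 26.8% separated the groups upwards and 26.9% downwards, against 16.7% in each direction by chance. At an unadjusted p under 0.05, 2182 genes were higher and 1570 lower with TMM, but the balance turned with upper-quartile scaling (1779 and 2161) and with library totals only (1877 and 1912). The counts of called genes depended on depth: they were 632 higher and 178 lower with all libraries thinned to the smallest total. They also changed with 1 library left out. The spread within groups then came from the other group's pair alone, so this cannot be put down to the library left out. Upper-quartile scaling gave 928 higher and 517 lower, so that 64.2% of calls were higher against 76.1% with TMM.

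The genes with large changes were mostly genes that rose. At 2-fold or more, 830 genes rose and 192 fell. At 4-fold or more, 478 rose and 24 fell, and at 8-fold or more 197 rose and 10 fell. Among the 8-fold changes, 2 genes that rose had no count in either control library and 1 that fell had none in either NMDA library. Their fitted fold changes therefore depend on the prior count. With these at a bound of 3 counts over the group, the medians above were the same. So few genes at the extreme could not move a median, so this is no check on their fold changes. Without NMDA 2 there were 1060 higher and 527 lower genes at 2-fold and 554 and 66 at 4-fold, without control 1 there were 704 and 63 and then 460 and 15, and without NMDA 1 there were 299 and 24 at 4-fold. Thinning all libraries to the smallest total gave 510 and 112 at 2-fold and 250 and 12 at 4-fold, a filter at 5 CPM gave 393 and 129 and then 130 and 6, and loess offsets gave 120 lower genes at 2-fold.

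**Figure D1:**
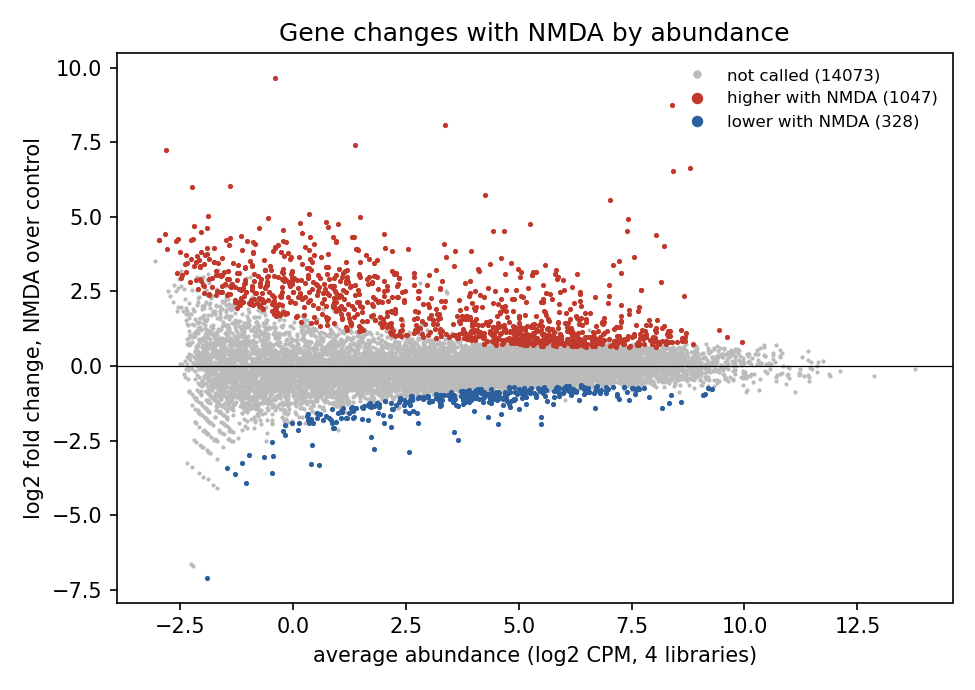
Average abundance (x axis, log2 CPM over the 4 libraries) against the log2 fold change of NMDA over control (y axis) for the 15448 tested genes. Red points are the 1047 genes higher with NMDA, blue points the 328 lower and grey points those not called; at 4-fold or more there are 478 upwards and 24 downwards.

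The parts of the libraries held by the called genes are given as sizes only, since their direction was fixed by calling the genes on these same libraries. The genes that rose held 2.91% ± 0.310 of gene counts in control and 6.70% ± 0.00105 in NMDA (SD, n = 2). The genes that fell held 1.87% ± 0.175 in control and 0.950% ± 0.126 in NMDA. The 10 most abundant genes of each library took 5.31% ± 0.0765 of its counts in control and 4.66% ± 0.387 in NMDA.

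Genes that rose were found at every level of abundance, and few of the least abundant genes were called lower. Of the 2354 genes with an average log2 CPM under 0, 222 rose and 14 fell. Between 0 and 2, 192 of 2153 genes rose and 54 fell. Between 2 and 4, 156 of 2992 rose and 92 fell, the largest share of falls at any level (3.07%). Between 4 and 6, 258 of 4390 rose and 107 fell. Between 6 and 8, 179 of 2816 rose and 53 fell. Above 8, 40 of 743 rose and 8 fell. In simulated counts of this comparison, over all levels, 4-fold decreases were called less often (78.8%) than 4-fold increases (91.8%).

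Some genes lay on opposite sides of 1 CPM in the groups, a limit set for description that is above the detection floor of each library. In both NMDA libraries 237 genes were at 1 CPM or more and in both controls under it, and 172 of them were called higher. In the opposite direction 137 genes were at 1 CPM or more in both controls and under it in both NMDA libraries, and 27 of them were called lower. The others in each direction were not called. The other 2 ways of splitting the libraries into pairs gave between 35 and 40 such genes in either direction. Each pair then holds a control and an NMDA library, so these counts are no measure of chance.

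Among genes with an average log2 CPM of 3 or more, the largest rise was that of ENSRNOG00000046667, from 1.03 and 1.98 CPM in the controls to 669 ± 344 CPM in NMDA (SD, n = 2). Its log2 fold change was 8.75 with a standard error of 0.46 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.61e-07), and over the alternatives it lay between 8.09 (without NMDA 2) and 9.33 (without control 2). It was counted 59 and 193 times in control 1 and 2, and 14491 and 13360 times in NMDA 1 and 2, so its CPM in NMDA 2 was 2.15 times that in NMDA 1. ENSRNOG00000056153 rose from 0.0687 ± 0.0478 CPM to 21.3 ± 0.469 CPM, a log2 fold change of 8.07 with a standard error of 0.41 (edgeR, Benjamini-Hochberg adjusted p = 3.61e-07). Its control level rests on 2 and 10 counts, which together give 0.0775 CPM with an exact 95% Poisson interval of 0.0400 to 0.135 that covers counting error only. Over the alternatives its log2 fold change lay between 7.21, after thinning, and 9.11, without control 2. The largest fall at an average log2 CPM of 3 or more was that of ENSRNOG00000007508, from 20.7 ± 1.97 CPM to 3.90 ± 1.15 CPM. Its log2 fold change was -2.46 with a standard error of 0.29 (edgeR, Benjamini-Hochberg adjusted p = 0.000164). Some less abundant genes fell further. ENSRNOG00000033026 went from 18.8 ± 3.41 CPM to 4.31 ± 1.73 CPM, a log2 fold change of -2.20 with a standard error of 0.31 (edgeR, Benjamini-Hochberg adjusted p = 0.000797).

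**Figure D2:**
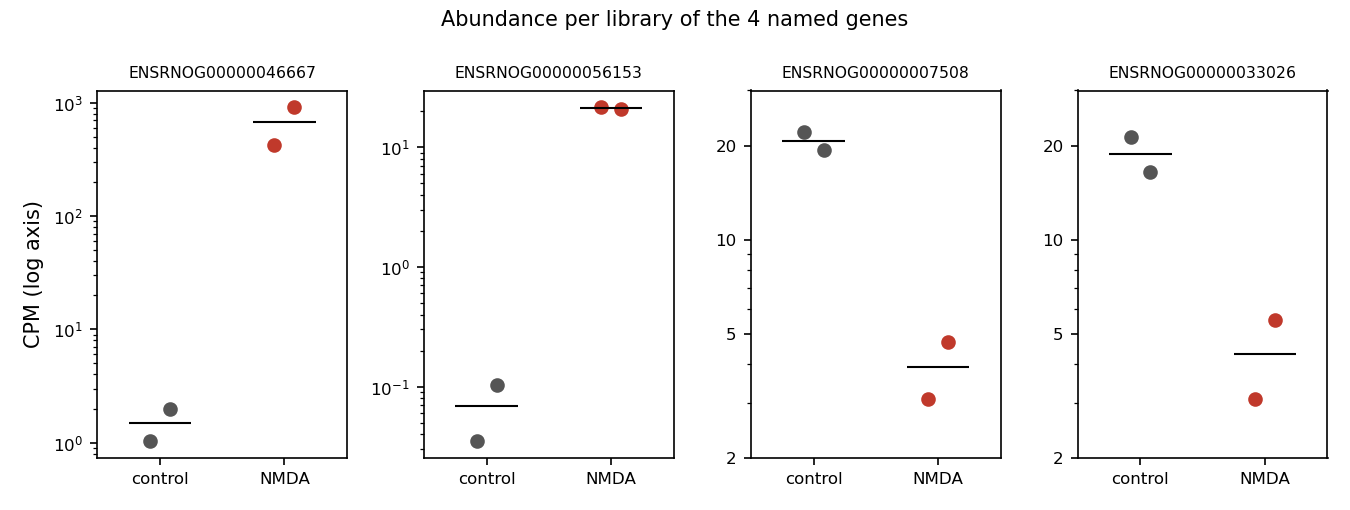
CPM (y axis, log scale, with its own range in each panel for the genes that rose and a shared range for those that fell) of the 4 genes in each library, by group (x axis). Points are libraries and lines are means of 2; both NMDA libraries lie on the same side of both controls in each panel, as for ENSRNOG00000046667 with 1.03 and 1.98 CPM in control and 425 and 912 CPM in NMDA.

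The NMDA libraries differed from each other more than the controls did. Among the 7949 genes with an average log2 CPM of 4 or more, the SD of the log2 ratio between replicates was 0.398 in NMDA and 0.261 in control. In these genes, 143 differed 2-fold or more between the NMDA libraries and 16 between the controls. The NMDA libraries were shallower, and these counts were not repeated at equal depth. After thinning to the smallest total the SDs were 0.404 in NMDA and 0.311 in control. NMDA 1 had the larger response in 300 of the 477 genes that rose and in 122 of the 168 that fell at this level of abundance. Of the 1047 genes that rose, 10 were less than 1.5-fold above the control mean in NMDA 1 and 50 in NMDA 2, and none in both.

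**Figure D3:**
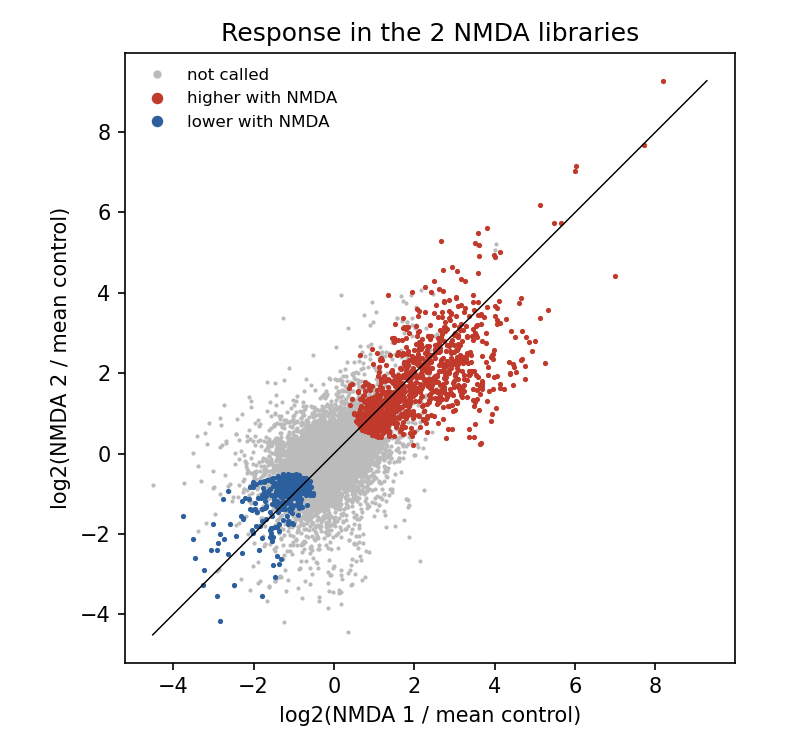
Log2 ratio to the control mean in NMDA 1 (x axis) and in NMDA 2 (y axis) for each tested gene, with genes higher in red, lower in blue and not called in grey. The line marks equal response; the genes that rose had a median of 1.80 in NMDA 1 and 1.52 in NMDA 2.

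In the authors' deposited table, 1574 genes had an adjusted p under 0.05, 1068 of them higher and 506 lower in NMDA. The authors' deposited table and the edgeR test shared 1245 calls, 933 higher and 312 lower, and 0 had opposite signs. A further 329 genes were called in the authors' deposited table alone and 130 by the edgeR test alone. Fold changes of the 4 genes above were smaller in the authors' deposited table, where ENSRNOG00000046667 had the largest, a log2 fold change of 7.36 with a standard error of 0.29. For ENSRNOG00000007508 the authors' deposited table gave -2.16 with a standard error of 0.26. The DESeq2 fit among the alternatives gave 8.78 for ENSRNOG00000046667 and -2.46 for ENSRNOG00000007508, close to edgeR. The edgeR fit with the authors' size factors gave 8.74 and -2.48, so those factors hardly changed these fold changes. Why the deposited fold changes were smaller was not tested further.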

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

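Thinning, loess offsets and the crossed block were chosen after the result was seen. The number of genes higher in NMDA, 1047, stayed within 1.5 times under 16 of 19 alternatives, and the number lower, 328, under 10. Requiring 5 CPM in 2 libraries gave 566 higher genes among the 10686 tested. Thinning gave 632 higher and 178 lower. The lower count was 501 with DESeq2, 517 with upper-quartile scaling and 513 with library totals only; the cause was not tested. It was 192 at an absolute log2 fold change of 1 or more and 737 at an adjusted p under 0.1, which follow from the thresholds. Leaving out 1 library gave 707 to 1769 higher and 67 to 1158 lower genes, with a lone library assumed to vary like the other group. The overlap with the calls from all 4 libraries was largest without NMDA 2, which was also the fit of these with the most calls. More calls give more overlap, so this does not show which library mattered least. No gene called both in an alternative and in the edgeR test had opposite directions. With the replicate number as a block there were 1118 higher and 403 lower genes, so neither count moved by over 1.5 times. Across genes, libraries with the same number did not deviate together (r = -0.08 over all tested genes, -0.21 at an average log2 CPM of 4 or more). A crossed replicate block gave 957 and 273. At 2-fold or more, 304 genes were lower at an adjusted p under 0.1 and 124 with the crossed block, against 192. At 4-fold or more, 40 were lower at an adjusted p under 0.1, against 24. The 4 genes given by ID kept their direction and call under all 19, and the largest adjusted p was that of ENSRNOG00000033026, which ranged from 2.02e-09 to 0.00539 (edgeR, DESeq2 and limma, Benjamini-Hochberg). The median log2 fold change of genes at an average log2 CPM of 6 to 8, 0.07, ranged from -0.02 (upper quartile) to 0.09 and was 0.02 without NMDA 1. That at 0 to 2, -0.14, ranged from -0.23 (upper quartile) to -0.01 (loess) and was -0.10 without control 2; the 5 CPM filter gave no value. Depth limits low genes most, in NMDA 2. Gene lists (camera included) and control genes were not run, because the gene table used here held no Ensembl IDs to match.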

Other observations

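For the excess of rises, the tests with thinning, with abundant genes and with changes of 4-fold or more were chosen after the result was seen; the tests of the spread between NMDA libraries were not.

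Of the 1375 calls 76.1% were rises, and this share was 91.3% without control 1 and 60.4% without NMDA 2. The lower depth of the NMDA libraries is argued against, since with every library thinned to the smallest total 78.0% of calls were rises (exact 95% binomial interval 75.0 to 80.8, counting error only). Falls being harder to call at low counts is argued against as the whole cause, since 74.0% of calls at an average log2 CPM of 4 or more were rises (70.4 to 77.3). Among changes of 4-fold or more, at least 93.1% were rises under each scaling tried. The median log2 fold change of all tested genes was -0.015 with TMM, -0.079 with library totals only and -0.102 with upper quartile. Shifts of that size can hardly turn changes of 4-fold or more. The choice among these scalings therefore does not explain their excess of rises, and a larger shift was not tested. Scaling stays open for smaller changes. With upper-quartile scaling 72.8% of 2-fold calls were rises (70.0 to 75.5). At an unadjusted p under 0.05 (edgeR) it gave 1779 rises and 2161 falls, and library totals only gave 1877 and 1912. Such a shift moves all genes alike. That large changes are mostly rises may be a response to NMDA, as a hypothesis found and tested on the same libraries; without NMDA 2 the share at 4-fold or more was 89.4%.

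The NMDA libraries differed more from each other than the controls did. Depth is argued against as the whole cause, since after thinning to the smallest total the SD of the log2 ratio was 0.404 in NMDA and 0.311 in control, a ratio of at least 1.28 in 20 thinnings. Among the 2458 abundant genes with an unadjusted p of 0.5 or more (edgeR), the ratio was at least 1.29. This cannot decide whether the difference was confined to the genes that NMDA changed. The p comes from these same libraries, and a gene changed unequally in the NMDA libraries can have a high one. A larger response in NMDA 1 throughout cannot be told apart from a mixed difference, since NMDA 1 had the larger response in 66.4% of the genes that rose and 68.6% of those that fell, between the bounds of 60% and 70% set beforehand. The protocols name several exposures and culture ages, so a difference in treatment or culture between the NMDA samples stays open and untested.

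The 4 libraries have 3 splits into pairs, which is too few for a share under 0.05. The real split called 1375 genes (edgeR), and the highest of the other 2 called 0, with 116 and 83 genes at an unadjusted p under 0.05 in those 2. Each of those 2 puts a control and an NMDA library in the same group. A difference between control and NMDA then widens the spread within groups, so their low counts are no measure of chance. Of the 3 splits, 1 called as many as the real one, the real one itself.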
